A study of Mus musculus with 2 samples.

How the data were processed

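Cultured rib chondrocytes of mice aged 5 days were compared by Affymetrix Mouse Genome 430 2.0 arrays, with 1 wild-type array and 1 miR-140 knockout array, grouped by their sample titles. Per the labels' protocols, RNA was extracted with ISOGEN, and biotin-labelled antisense cRNA was made from total RNA by a 3′ amplification kit. The deposited values are log2 signals made by the authors with Robust Multichip Average (RMA), per the labels' design text, which corrects background, normalizes the arrays to a common distribution and summarises the probes of a probe set. Per the submitters' processing notes, this was run in Affymetrix Expression Console 1.1. That the scale is log2 was read from the values, which run from 3.24 to 14.2. Which arrays were normalized together is not given in the sources used here. The sorted values of both arrays differ by at most 0.157, so a difference shared by most genes would have been removed. RMA also compresses differences of dim probe sets, and 962 probe sets had exactly equal values in both arrays. The design text names NIA Array Analysis for statistics; its output was not used here.

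The table holds 45101 probe sets, of which 64 are Affymetrix controls. Gene symbols came from the platform annotation. A single symbol was listed for 34945 of the other probe sets, several symbols for 932, which name no gene here, and 9160 were not listed and are unnamed here. Of the 34945, 34741 were found by Entrez identifier in a RefSeq gene table of GRCm38.p6, none changed symbol, and 204 were not found and kept the platform's name. That table was also used to find the genes near Wwp2 and those on the X and Y chromosomes. No coordinates are given because no genome build is named for the array values.

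For each of 18193 genes the probe set with the highest mean of both arrays was kept. A gene was compared if the higher of its log2 values was at least 7, which left 9897 genes. The knockout minus wild-type difference was taken on the log2 scale, and differences of at least 2-fold were counted. With 1 array per group no test is possible, so no p-value or standard error is given and the number of arrays limits the precision. Signal under the floor is close to background, and folds that involve it understate or misstate the difference.

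Before the data were examined, 30 gene lists were fixed. They cover cartilage matrix, chondrogenic transcription factors, hypertrophy and mineralization, matrix proteases, protease inhibitors, proposed miR-140 targets and 4 signalling groups (BMP and TGF-beta; hedgehog, PTHrP and FGF; IGF; Wnt). They also cover cell cycle, markers of other cell types (fibroblast and perichondrium, osteoblast, osteoclast, skeletal muscle, macrophage and leukocyte, neutrophil and erythroid, endothelial, adipocyte, smooth muscle and pericyte), interferon response and inflammation. The others are immediate early and heat shock genes, hypoxia and glycolysis, unfolded protein response, microRNA pathway, Mir140 host gene and neighbours, sex-linked genes, ribosomal proteins and oxidative phosphorylation. Of their 662 symbols, 49 were not named here. Genes within 5 Mb of Wwp2 were a further planned list. The median difference of a list's members above the floor was placed as a percentile among 10000 random lists of the same size, matched on mean signal in 20 bins. A list with at least 3 such members was said to stand apart under percentile 2.5 or over 97.5. Some genes are in several lists, Mmp13 among them.

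The named genes were also set by rule. They are the 12 farthest genes in each direction above the floor without predicted or clone symbols (1 such gene was at least 2-fold higher and 1 lower), all cartilage matrix genes and proposed targets above the floor, and up to 4 members with the largest differences from each other list. Wwp2 and 4 neighbours were added, and it is said where probe sets of a named gene above the floor differ in sign.

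Alternatives were median centring, a further quantile normalization, lowess centring with a span of 0.2, floors of 6 and 8 and no floor, the mean of all probe sets of a gene, probe sets of 1 transcript only, a 1.5-fold threshold, low values raised to 7, and random lists without matching. Results without X and Y genes, without genes whose probe sets disagree, without Adamts5 and Mmp13, and amino acid response lists were added after the data were seen. A planned comparison of genes with miR-140 seed matches in their 3′ untranslated regions, for both strands of the microRNA, was not run because no transcript sequences were used here.

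Counts and percentiles were tested on simulated data. With 200 changed genes among 9897, the 2-fold count recovered 100% of genes changed by 1.5 or 2 on the log2 scale in either direction and 0% of those changed by 0.5. Lists of 20 genes fell outside the percentile limits in 5% of 200 draws with no shift, in 41% with a shift of 0.1 and in 92% with a shift of 0.2. The simulated noise had a single assumed size, was independent between genes and held no spread between cultures. These rates follow from that noise and check the code. They are not rates for these arrays, whose differences had an SD of 0.332 across genes. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.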

Results

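Messenger RNA levels were measured on 2 microarrays hybridised with total RNA from cultured rib chondrocytes, the cells that make cartilage, taken from mice aged 5 days. One culture was wild type and the other lacked miR-140, a microRNA made at high level in cartilage, and both carried the same strain label naming C57BL/6 and CBA. The arrays were made to search for messenger RNAs that miR-140 may repress, so the comparison asked which transcripts stood higher or lower in the knockout array. Each group has 1 array, which leaves no spread between cultures to set a difference against. Every difference below therefore describes this pair of arrays, is given as the log2 signal of the knockout minus that of the wild type, and has no replicate check.

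The deposited RMA values spanned 3.24 to 14.2 on the log2 scale in the wild-type array and 3.28 to 14.1 in the knockout array, with medians of 6.29 and 6.30. Of 18193 genes with a probe set of their own, 9897 (54.4%) reached a log2 signal of 7 in at least 1 array and were compared. Across these genes the arrays had a Pearson correlation of 0.970, which describes genes and not replicates. The median difference was -0.05 and the central 95% of genes lay between -0.69 and 0.47. At least 2-fold higher signal in the knockout array was found for 47 genes (0.475%) and at least 2-fold lower signal for 121 genes (1.22%). A 4-fold difference was reached by 5 genes in the higher direction and 28 in the lower.

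The array carries no probe set for the mature miR-140 strands, so the deleted product itself was not measured. The gene Mir140 lies in an intron of Wwp2, which encodes a ubiquitin ligase. All 6 Wwp2 probe sets had lower signal in the knockout array. The probe set used for the gene read 9.65 in the wild type and 7.13 in the knockout, a difference of -2.52 (5.72-fold lower). The 3 others above the floor differed by -4.50, -1.88 and -0.99. Which part of the locus was removed is not given in the sources used here, so these values do not test the knockout label. Neighbouring genes showed smaller differences: Nqo1 stood at -0.51, St3gal2 at 0.43, Psmd7 at 0.28 and Sntb2 at -0.22. The 15 members of the host gene and neighbour list above the floor had a median of -0.06, at percentile 42.4 of 10000 random lists matched on signal. The 81 genes within 5 Mb of Wwp2 had a median of -0.03 at percentile 72.4, with Cdh11 at 0.75 and Smpd3 at -0.74 farthest from 0.

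Transcripts of cartilage matrix were lower in the knockout array. Of the 26 listed genes above the floor, 24 had lower signal and 22 were at least 2-fold lower, while none was 2-fold higher. Acan, the core protein of aggrecan, read 12.02 in the wild type and 7.99 in the knockout (16.3-fold lower). Col9a2 and Col9a3, chains of type IX collagen, were 13.9-fold and 7.92-fold lower, and Col9a1 was 2.98-fold lower. The knockout signal of Col9a2, 6.06, lies under the floor, and its difference of -3.80 becomes -2.86 when low values are raised to 7; Col9a3 (-2.99) stands at -2.39 with the mean of its probe sets. Ucma, a Gla-rich cartilage protein, was 12.9-fold lower. Col2a1, the main cartilage collagen, read 13.98 and 11.98 (4.0-fold lower). The median of the list was -1.62, a 3.08-fold lower signal, and lay below all 10000 matched random lists.

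Within this list Snorc, a chondrocyte proteoglycan, was 7.41-fold lower, the link protein gene Hapln1 5.46-fold lower, the chondromodulin gene Cnmd 5.28-fold lower and Ncmap 5.10-fold lower. The type XI collagen chains differed by -2.09 for Col11a2 and -1.22 for Col11a1, and Col27a1 differed by -2.02. Scrg1 stood at -2.06, Comp at -1.67, Cytl1 at -1.53, Epyc at -1.51, Matn3 at -1.30, Matn4 at -1.27 and Fmod at -1.12. Papss2 and Chst11, enzymes of sulphate donor and chondroitin sulphate synthesis, stood at -1.46 and -1.14, and at -0.79 and -0.78 with the mean of all their probe sets. Prelp (-0.37), Cilp2 (-0.22), Edil3 (0.25) and Matn2 (0.95) made up the remainder. Prelp has a further probe set above the floor, at 0.05, and Matn2 reached 2-fold higher signal (1.04) with probe sets of 1 transcript. The same pair of arrays also differed in Xist (3.59) and Y-linked genes, in fibroblast markers (median 0.20) and in 18S ribosomal RNA probe sets (median -0.52).

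**Figure D1:**
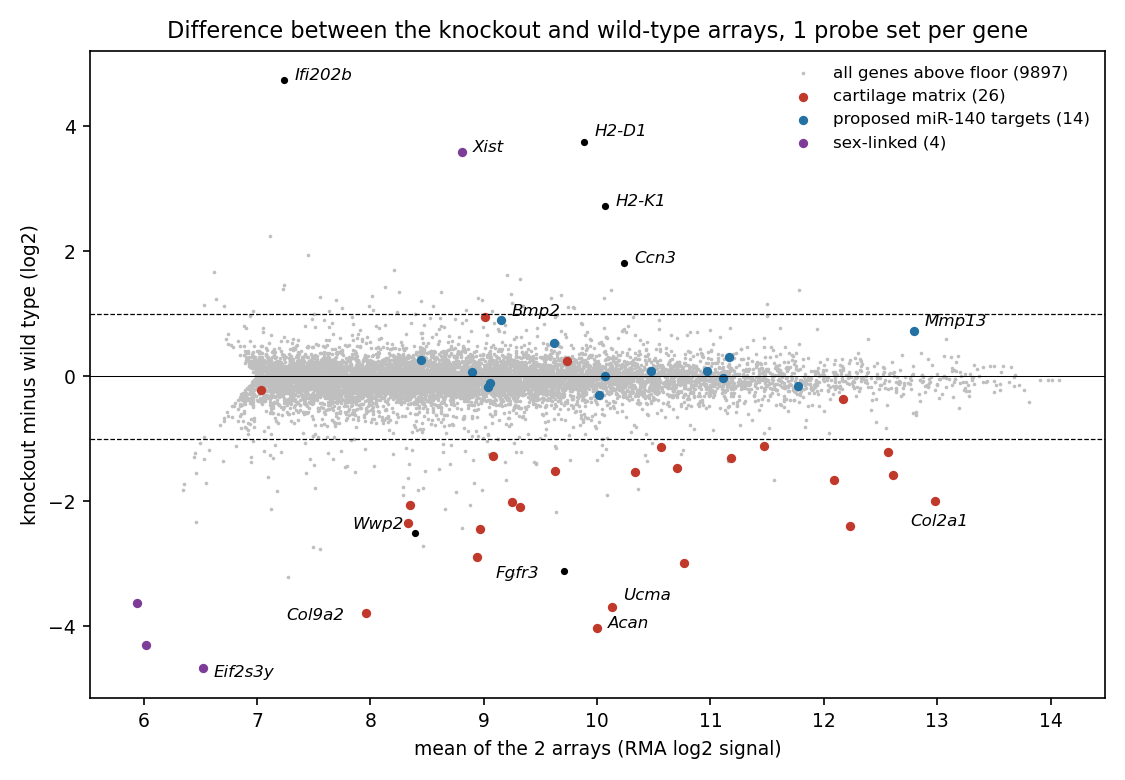
Difference between the arrays (knockout minus wild type, log2) against the mean log2 RMA signal of both, with 1 point for each of 9897 genes; dashed lines mark a 2-fold difference. Cartilage matrix genes (red) lie mostly under the lower line, with Acan at -4.03 and Col2a1 at -2.0, the 14 proposed miR-140 targets (blue) lie between the lines, and the 4 sex-linked genes (purple) lie at the edges.

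Among transcription factors of chondrocytes, Sox9, the factor needed for chondrocyte identity, differed by -1.18 (2.26-fold lower), and by -0.85 with the mean of its probe sets. Its partner Sox6 stood at -0.49 and Nfatc1 at -0.30. The 8 genes of that list above the floor had a median of -0.21 at percentile 2.90, just inside the limit of 2.5 used to say that a list stood apart. It passed that limit in 5 other settings, at percentiles of 0.30 to 1.17, but with the mean of all probe sets the median was -0.08 at percentile 19.9. Hypertrophy and mineralization genes had a median of -0.07 over 8 members (percentile 38.4). Col10a1, the collagen of hypertrophic chondrocytes, was 3.28-fold lower (7.41 and 5.69). Its knockout signal lies under the floor, and the difference is -0.41 when low values are raised to 7. Mmp13, also in this list, went the other way at 0.73 (12.43 and 13.16).

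Matrix proteases had slightly higher signal in the knockout array. Of 21 members above the floor, 17 were higher and the median of 0.23 lay above all 10000 matched random lists. Fibroblast and perichondrium markers had a median of similar size, 0.20, also above all random lists. Mmp3 (stromelysin) was 2.23-fold higher and was the 1 member past 2-fold. Mmp13, a collagenase, was 1.66-fold higher (12.43 and 13.16), and Ctsk and Adamts9 were each 1.40-fold higher. For Adamts9 a further probe set differed by -0.12. Protease inhibitors had no common direction, with 4 of 9 higher and a median of -0.09 at percentile 29.3. The median was -0.02 with a floor of 6, and turned to 0.06 with no floor (percentile 93.0) and with probe sets of 1 transcript (85.7). A2m was 3.42-fold lower, Timp3 1.78-fold lower and Reck 1.73-fold lower, whereas Serpinf1 was 1.67-fold higher.

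Genes that earlier work had proposed as miR-140 targets differed little between the arrays. Of 18 listed genes, 14 were above the floor, 9 of them higher and 5 lower in the knockout array, and none reached 2-fold. Bmp2, a bone morphogenetic protein, was 1.87-fold higher, Mmp13 1.66-fold and Igfbp5, an insulin-like growth factor binding protein, 1.45-fold higher. Adamts5, an aggrecanase, was 1.23-fold higher, and its 3 probe sets above the floor differed by 0.16, 0.30 and 0.49. Nrip1 stood at 0.26, Pdgfra at 0.08, Septin2 at 0.08, Rala at 0.07 and Sp1 at 0.00. Lower signal was found for Dnpep (-0.03), Smad3 (-0.12), Cxcl12 (-0.16), Vegfa (-0.18) and Slc38a1 (-0.31). Probe sets above the floor differed in sign for Cxcl12 (-0.53 to 0.18), Slc38a1 (-0.31 to 0.11), Dnpep (-0.03 to 0.12), Smad3 (-0.12 to 0.06) and Sp1 (-0.02 to 0.00). A Pdgfra probe set of lower signal differed by 1.20.

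The median of the proposed targets was 0.07, at percentile 97.7 of matched random lists, just past the upper limit for standing apart. Of 11 other settings, among which median centring cannot change a percentile, the list fell inside the limit in 6. It lay at 96.4 after a further quantile normalization and at 89.6 without Adamts5 and Mmp13, which are also matrix proteases. In the settings where the call held, the list lay at 97.6 (floor of 8) to 99.5 (mean of all probe sets, median 0.16). Hdac4 (0.21), Fgf9 (0.02), Jag1 (0.17) and Il1rap (-0.02) stayed under the floor in both arrays. The remaining lists of the comparison were fixed without regard to miR-140 sites, since no 3′ untranslated sequences were used here.

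Signalling lists were mixed in direction. In the hedgehog, PTHrP and FGF list, Fgfr3, a receptor of growth plate chondrocytes, read 11.27 in the wild type and 8.15 in the knockout (8.73-fold lower), and its other probe set differed by -1.30. Spry2 (0.85) and Spry1 (0.75), feedback inhibitors of FGF signalling, were higher, and Smo stood at -0.60. With the mean of their probe sets Spry2 stood at 0.40 and Smo at -0.25. The list median was -0.16 at percentile 3.66, and turned to 0.14 at percentile 98.7 with the mean of all probe sets of a gene. The BMP and TGF-beta list had a median of -0.06 over 30 genes (percentile 43.2; 0.03 with the mean of all probe sets), with Id4 3.26-fold lower, Tgfb2 2.27-fold lower (-1.18, and -0.92 with probe sets of 1 transcript) and Grem1 1.64-fold higher. In the Wnt list, 13 of 17 genes were lower and the median was -0.11 (percentile 14.1; -0.02 with the mean of all probe sets). Wif1, a secreted Wnt inhibitor, was 3.61-fold lower and Frzb 1.95-fold lower, while Dkk3 was 1.70-fold higher. The IGF list had 6 of 12 genes higher and a median of -0.03 (percentile 66.3). Igf1 was 2.45-fold higher and Igfbp2 1.88-fold lower. The median was 0.15 at percentile 99.9 with no floor and 0.11 at percentile 97.9 with the mean of all probe sets.

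Markers of other cell types that a rib culture could hold were compared in the same way. Fibroblast and perichondrium markers were higher for 17 of 23 genes, with a median of 0.20 above all 10000 matched random lists. Col3a1 was 2.60-fold higher, Lum 1.95-fold and Fbln2 1.65-fold higher, but Postn differed by -1.26. Of 4 osteoblast markers above the floor, Tnfrsf11b was 2.55-fold lower and Omd 1.87-fold lower, and Col1a1 was 1.21-fold higher. Their median of -0.51 lay at percentile 0.45, but it was -0.02 at percentile 59.8 with a floor of 6. Adipocyte markers had a median of 0.15 over 7 genes at percentile 98, with Lpl 2.16-fold and Fabp4 1.42-fold higher and Cebpa 1.39-fold lower. That list fell inside the limit in 3 other settings. Smooth muscle and pericyte markers (-0.10, 6 genes, percentile 29.2), endothelial markers (-0.02, 5 genes, percentile 61.5) and macrophage and leukocyte markers (0.01, 5 genes, percentile 74.4) stayed inside the limits. With probe sets of 1 transcript only, the smooth muscle list turned to 0.04 (percentile 79.3) and the leukocyte list stood at 0.18 (percentile 98). Of the osteoclast list Ctsk was above the floor, and of the skeletal muscle list Des (0.14). The neutrophil and erythroid list had 2 such genes, Car2 (0.24) and Elane (-0.03).

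**Figure D2:**
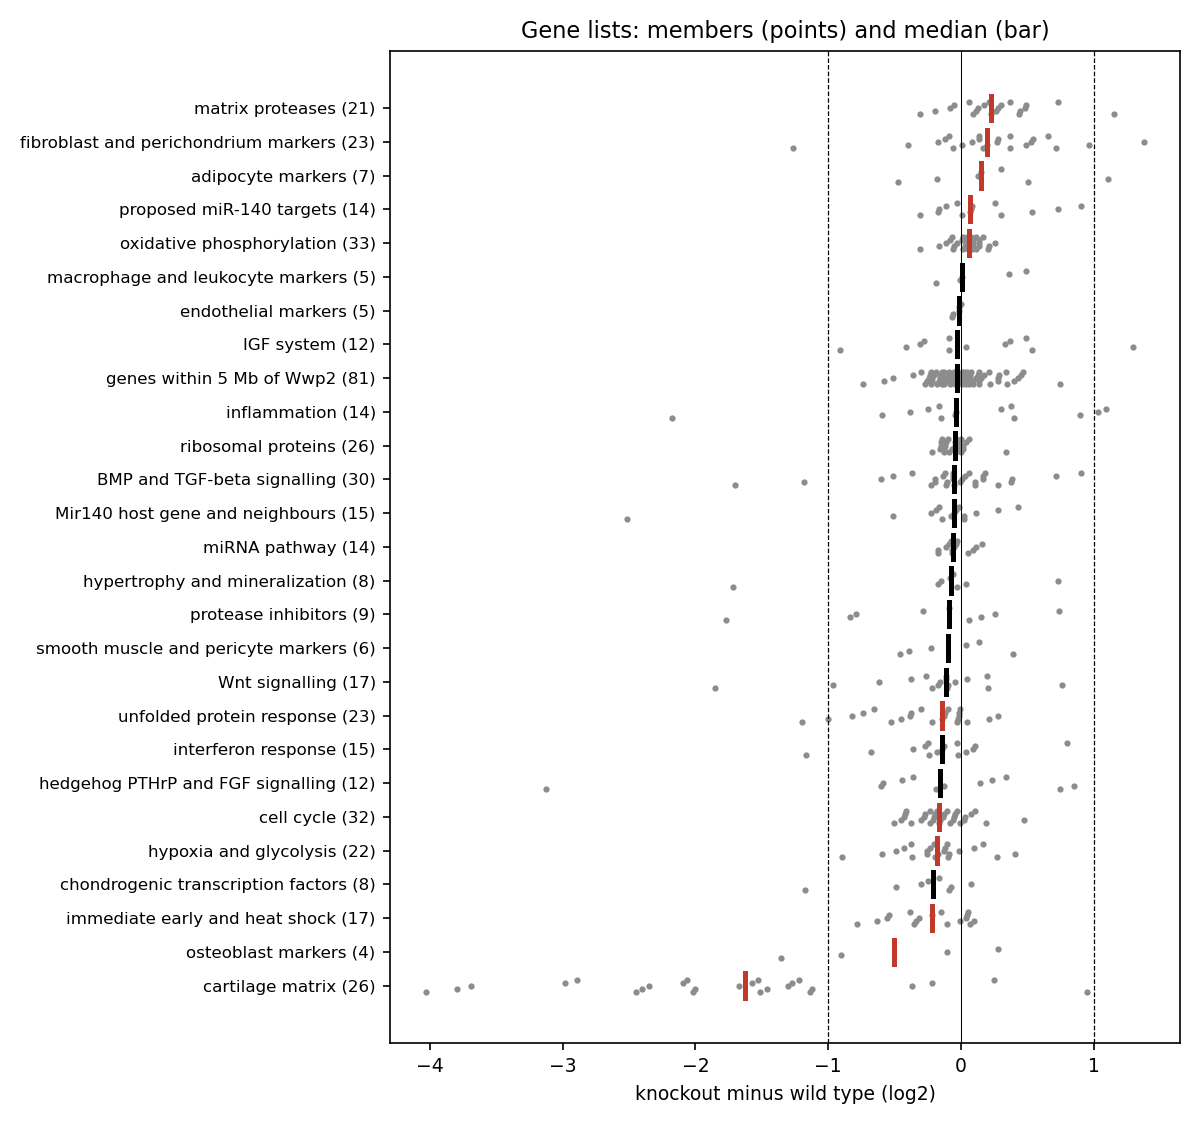
Differences (knockout minus wild type, log2) of the members above the floor of each gene list (points) with the list's median (bar, red where it stood apart from matched random lists); the number of members is in parentheses. The sex-linked list and the lists with fewer than 3 members above the floor are not drawn. The cartilage matrix median of -1.62 lies far to the left of all other medians drawn, which span -0.51 to 0.23.

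Several lists of growth, stress and metabolism had small differences in a common direction. They were of the size of the fibroblast marker median (0.20), and the same arrays also differed in 18S ribosomal RNA probe sets (median -0.52) and in Xist (3.59) and Y-linked genes. Cell cycle genes were lower for 26 of 32 members, with a median of -0.16 at percentile 0.38 and no member past 1.5-fold. Mcm6 stood at -0.50, Mcm2 at -0.46 and Ccna2 at -0.43, whereas Ccnd1 (cyclin D1) stood at 0.47. Immediate early and heat shock genes were lower for 12 of 17 members, with a median of -0.22 at percentile 0.29 and with Hspa1b 1.55-fold, Dusp1 1.47-fold and Fos 1.45-fold lower. Hspa1a was farthest at -0.78, but its knockout signal lies under the floor. With low values raised to 7 it stood at -0.07. Genes of hypoxia and glycolysis were lower for 18 of 22 members, with a median of -0.18 at percentile 0.36. Ero1a was 1.86-fold lower (-0.89, and -0.60 with the mean of its probe sets), Ndrg1 1.51-fold and P4ha2 1.41-fold lower. Unfolded protein response genes were lower for 20 of 23 members, with Trib3 2.30-fold, Chac1 2.00-fold and Ddit3 1.76-fold lower. Ddit3 stood at -0.47 with the mean of its probe sets. These named members are also in an amino acid response list chosen after the data were seen. The upper quartile of the unfolded protein response members, -0.02, lay above the median of all genes (-0.05), so the count overstates a shared fall. The list's median of -0.14 lay at percentile 2.26 and at 2.60 to 3.48 in 4 other settings, which ended the call.

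Oxidative phosphorylation genes were higher for 25 of 33 members, with a median of only 0.06 at percentile 99.8. It lay at 93.6 with the mean of all probe sets. Cox8a stood at 0.21, Cox6c at 0.26 with a further probe set at -0.05, and Uqcrc2 at -0.31. Ribosomal protein genes had a median of -0.04 over 26 genes (percentile 66.1), with Rps19 farthest from 0 at 0.34. Genes of the microRNA pathway had a median of -0.06 over 14 genes (percentile 45.2), and Tnrc6b stood at -0.18. Interferon response genes had a median of -0.14 over 15 genes at percentile 7.55. Ifit1 was 2.24-fold lower and Usp18 1.60-fold lower, and Stat2 1.74-fold higher. The wild-type signal of Stat2 lies under the floor, and its difference is 0.28 with low values raised to 7. The list passed the limit with no floor (percentile 1.34) and with the mean of all probe sets (0.17). Inflammation genes were split, with 6 of 14 higher and a median of -0.04 (percentile 55.2). Lcn2 was 4.52-fold lower, while Ptgs2, Vcam1 and Cxcl5 were 2.13-fold, 2.05-fold and 1.86-fold higher. With probe sets of 1 transcript only Vcam1 differed by 2.04 and the inflammation median was 0.30 (percentile 99.975).

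In total, 12 of 28 lists with a percentile stood apart, where 1.4 would by chance if their members were independent of each other, which they are not. The 12 include the sex-linked list. In 7 of the 12 the call held in all other settings run for that list, and in 5 it was lost in at least 1 setting. Median centring is among these settings and cannot change a percentile.

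Genes with the farthest differences included transcripts of the sex chromosomes and of the major histocompatibility complex. Xist, the RNA of the inactive X chromosome, read 7.01 in the wild type and 10.60 in the knockout, a difference of 3.59, and its other probe set above the floor differed by 5.49. The Y-linked genes Eif2s3y, Uty and Kdm5d were 25.6-fold, 19.7-fold and 12.3-fold lower in the knockout array, with knockout signals of 4.18, 3.87 and 4.13. These lie under the floor, and with low values raised to 7 the differences are -1.86, -1.17 and -0.75. The sex-linked list thus has a median of -3.96 over 4 genes that do not share a direction. Sex is not given in the labels. The Y-linked genes read 8.86, 8.17 and 7.75 in the wild type and lay at background in the knockout, and Xist went the other way. The cultures thus differed in sex, or in the mix of sexes of the mice used. Without genes of the X and Y chromosomes, 45 genes were at least 2-fold higher and 113 at least 2-fold lower.

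Ifi202b, an interferon-inducible gene, read 4.87 and 9.61, a difference of 4.74. Its wild-type signal lies under the floor, and the difference is 2.61 with low values raised to 7. H2-D1 and H2-K1, class I histocompatibility genes, were 13.4-fold and 6.58-fold higher by the probe set used for each. The 7 H2-D1 probe sets above the floor ranged from -6.84 to 3.74, and the mean of all its probe sets differed by 0.28, so no direction is given for this gene. The 4 of H2-K1 ranged from -0.19 to 2.72, and the mean of its probe sets differed by 1.32. Among the other genes farthest in the higher direction, Cyp2f2 and Cyp7b1, cytochrome P450 enzymes, were 4.76-fold and 2.74-fold higher. Nr2f1, a nuclear receptor, was 3.85-fold higher. Ccn3 and Tgfbi, secreted matrix-associated proteins, were 3.50-fold and 2.93-fold higher. Mamdc2 (3.23-fold), Bnc1 (3.18-fold) and Rbm45 (3.07-fold) completed that group. With low values raised to 7, Cyp2f2 stood at 1.24, and Cyp7b1 (0.97) and Bnc1 (0.46) no longer reached 2-fold. The wild-type signal of Nr2f1, 6.47, also lies under the floor, so its fold too depends on background. In the lower direction, outside the cartilage and sex-linked lists, were Galc, a lysosomal galactosylceramidase (9.27-fold), Cdsn (9.03-fold), Fgfr3 and Ppp1r1b (6.82-fold). The knockout signals of Galc and Ppp1r1b lie under the floor, and both differ less with low values raised to 7 (-1.88 and -1.94). Galc has 2 further probe sets, both under the floor, at 0.28 and -0.06.

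**Figure D3:**
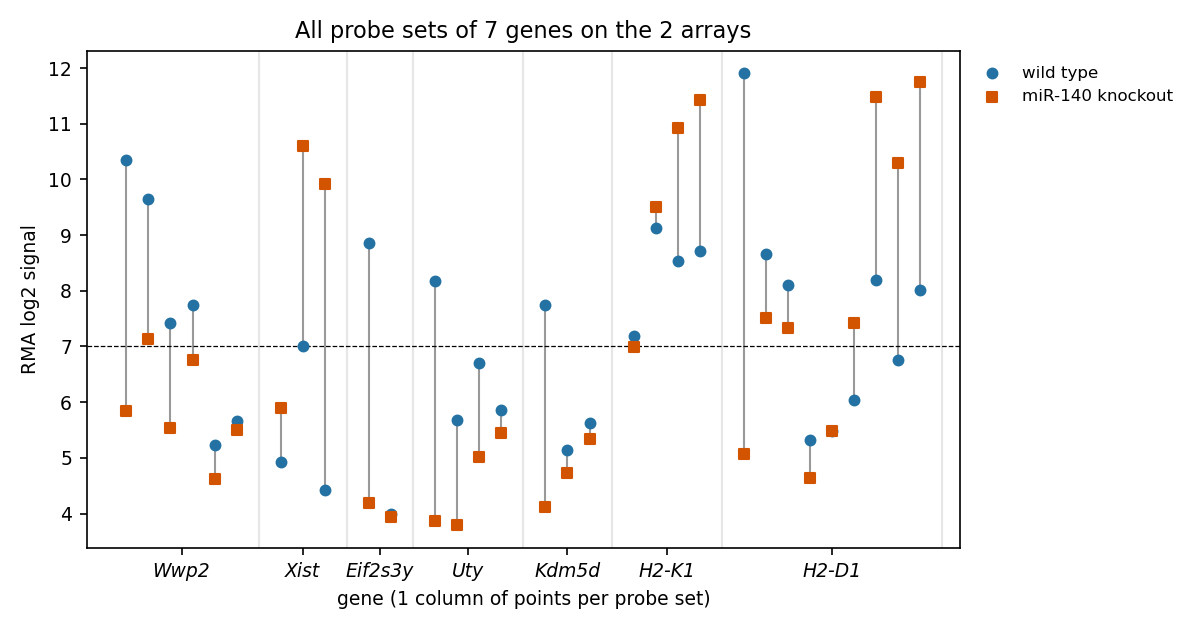
Log2 RMA signal of each probe set of 7 genes in the wild-type array (blue circles) and the knockout array (orange squares), with a line joining the pair; the dashed line is the floor of 7. All Wwp2 probe sets are lower in the knockout array, Xist and the 3 Y-linked genes differ in opposite directions, and H2-D1 probe sets differ from -6.84 to 3.74.

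Several probe sets of one gene were the nearest thing to a repeat measurement, and cover probe noise but not the spread between cultures. Of 3838 genes with more than 1 probe set above the floor, 2002 (52.2%) had differences of a single sign, and the pooled SD between probe sets of a gene was 0.27. No chance level for a single sign was worked out, so this share does not show that probe sets agree. Among the 63 genes that differed at least 2-fold, 60 (95.2%) had a single sign. They were picked by a large difference of 1 of those same probe sets, which favours a single sign. Their probe sets differed more in size, with a pooled SD of 1.09, or 0.55 without H2-D1. Hybridisation spikes differed by a median of 0.08 over 18 probe sets (-0.10 to 0.22) and poly-A spikes by 0.10 over 24 (-0.24 to 0.38). The 3 probe sets of 18S ribosomal RNA differed by -1.28 to -0.31. The 3′ minus 5′ signal of the Actb control probe sets was 0.81 in the wild type and 0.54 in the knockout, and that of Gapdh was 0.13 and -0.01.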

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

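The tests of RNA degradation, normalization, cell composition, histocompatibility alleles and an interferon response reported here were chosen after the patterns had been seen.

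Probe sets without a listed gene took no part in the comparison of named genes, and they also held differences. Of 9160 such probe sets 1546 were above the floor, and 15 were at least 2-fold higher and 13 at least 2-fold lower in the knockout array. The farthest were 1426438_at (10.64 in the wild type and 3.65 in the knockout) and 1452077_at (9.13 and 3.77) in the lower direction. Both lay at background in the knockout, as did the Y-linked genes Eif2s3y, Uty and Kdm5d. Ddx3y, also in the sex-linked list, had no named probe set. Which gene these probe sets measure is not known from the annotation used. In the higher direction they included 1441746_at (5.17 and 7.17). Among probe sets with several symbols, 2 were at least 2-fold higher and 0 lower.

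Cartilage matrix transcripts were lower in the knockout array, with a median of -1.62. RNA degradation in the knockout sample would raise the 3′ minus 5′ signal of the control transcripts there. It was lower for both Actb and Gapdh, and the higher of these changes was -0.13. Pyruvate carboxylase went the same way (3′ probe set -0.03, 5′ probe set 0.37, the 5′ one under the floor in both arrays). The 18S probe sets (-0.31 and -1.28) and those of the transferrin receptor (0.48 and 0.32, under the floor) went the other way. Among the poly-A spikes, DapX went the way of Actb (3′ 0.00 and 5′ 0.37), as did LysX (0.04 and 0.38, under the floor). PheX went the other way (0.15 and 0.10, under the floor). Such spikes are added and hold no RNA of the sample, so the Actb and Gapdh changes need not reflect its state. The controls were thus mixed and do not decide whether the RNA was degraded. Normalization that moves genes of like signal alike would leave the list among random lists matched on signal. The list median instead differed from the lowest of 10000 such lists by -1.38. These are the random lists used above, so this outcome was known beforehand and adds no evidence of its own. A lower share of chondrocytes in the knockout culture may contribute and cannot be told apart from lower expression per cell: medians of 4 lists of other cell types spanned 0.29, but this decides nothing, since 5 of 17 endothelial and 5 of 20 leukocyte markers were above the floor, most of them close to it. Loss of miR-140, sex and the state of each culture stay open too, since 1 array per genotype separates none of them.

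H2-D1, H2-K1 and Ifi202b differed strongly between the arrays. An interferon response in the knockout culture is argued against by the interferon list, whose median was -0.14, and by B2m (0.07), which is needed for class I presentation. Tap1 (0.04) and Psmb8 (0.10) are members of that list, lie close to the floor and are no separate support. Different alleles under the probes are a candidate explanation for H2-D1, because its probe sets above the floor ranged over 10.6 with both signs, the widest of 1387 genes with at least 3 such probe sets and beyond their 99th percentile of 1.47. The strain label names both C57BL/6 and CBA, so the cultures may carry different parental segments, but no genotype was tested and Ifi202b has 1 probe set. The wider effect of such segments on other transcripts stays open.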

How the results depend on the processing

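The settings without X and Y genes, without genes whose probe sets disagree in sign and without Adamts5 and Mmp13 were chosen after the data were seen. No paired analysis was possible because each group has 1 array; no array could be left out and no other split of the arrays exists. The planned seed-match results for both miR-140 strands and their alternatives were not run. With the 1.5-fold threshold 154 genes were higher and 352 lower. At 2-fold, the other 11 settings gave 40 to 56 higher and 90 to 130 lower. Raising low values to 7 must count the same genes as a floor of 8 (40 and 98 in both), so these are not separate checks. The cartilage matrix median stayed between -1.69 and -1.53, below all random lists. Of 66 named genes at least 2-fold apart, 55 stayed so in all settings run. The cause of the following moves was not tested.

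For proposed miR-140 targets the call was lost, with medians of 0.098 (further quantile normalization), 0.10 (lowess), 0.079 (probe sets of 1 transcript), 0.077 (without disagreeing genes), 0.072 (unmatched lists) and 0.036 (without Adamts5 and Mmp13). It was also lost for adipocyte markers (0.158 quantile, 0.167 lowess, 0.148 1 transcript), the unfolded protein response (-0.141 with floors of 6 and 8, no floor and unmatched lists), oxidative phosphorylation (0.048, mean of probe sets) and osteoblast markers (-0.121, no floor). Osteoblast markers turned to the other side of the random lists with a floor of 6 (-0.020).

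Lists that came to stand apart were chondrogenic factors (-0.248 floor 6, -0.274 floor 8, -0.207 no floor, -0.274 1 transcript and without disagreeing genes), IGF (0.15 no floor, 0.113 mean of probe sets), hedgehog, PTHrP and FGF (0.139 mean of probe sets), leukocyte markers (0.184 1 transcript), interferon response (-0.152 no floor, -0.245 mean of probe sets) and inflammation (0.301 1 transcript).

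Lists that moved inside the limits by more than the spread of random medians were, with the mean of probe sets, chondrogenic factors (-0.085), BMP and TGF-beta (0.030) and Wnt (-0.018). With probe sets of 1 transcript they were protease inhibitors (0.060), hedgehog, PTHrP and FGF (0.0084), smooth muscle (0.036) and interferon (-0.214). With other floors they were protease inhibitors (-0.017 floor 6, 0.060 no floor), smooth muscle (-0.229 floor 8) and interferon (-0.250 floor 8). With a further quantile normalization it was IGF (0.046). Median centring adds 0.05 to all genes and random lists alike and left all percentiles as they were, so BMP and TGF-beta (-0.0079), genes near Wwp2 (0.018) and ribosomal proteins (0.0033) shifted only with all genes. Ribosomal proteins stood at 0.00036 after quantile normalization and 0.0067 with lowess, where the median of all genes also lay closer to 0 (-0.02 in both). The scalings started from values already normalized and do not test the authors' normalization. Signal over background limits genes near the floor: Bnc1, Cyp7b1, Kdm5d and Col10a1 stood under 2-fold (0.46, 0.97, -0.75, -0.41) with low values raised to 7. Each of these genes read under 8 in both arrays, so that setting could not leave it at 2-fold. Their fall under 2-fold is therefore no evidence against a difference. Named genes that came to reach 2-fold were Matn2 (1.04) and Hspa1b (-1.05) with probe sets of 1 transcript, and Lum with median centring (1.01) and quantile normalization (1.0).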

Other observations

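The amino acid response lists below were chosen after the largest differences had been seen, as was the test of normalization; the test of a few extreme genes was set before the values of the members not looked at were seen.

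Genes of the amino acid response, the ATF4-driven programme of amino acid transport and synthesis, were lower in the knockout array. All 11 members noticed first were lower, with a median of -1.21, and 8 were at least 2-fold lower; they were picked for their low values and are no evidence of their own. Bcat1, a branched-chain aminotransferase, was 3.11-fold lower, Cth, which makes cysteine, 2.90-fold, and the transporters Slc1a5, Slc7a3 and Slc7a5 were 2.75-fold, 2.33-fold and 2.32-fold lower. With the mean of all probe sets Bcat1 and Slc1a5 stood at -0.92 and -0.80. Of 33 members not looked at before, 31 were lower and 11 were at least 1.5-fold lower. Atf5 was 1.76-fold lower, Ppp1r15a 1.74-fold and Psat1, an enzyme of serine synthesis, 1.73-fold lower. Gpt2 was 1.85-fold lower, but its probe sets above the floor ranged from -1.23 to 0.05. Gadd45a, higher at 0.66, was an exception named after its value was seen.

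A few extreme genes as the whole of this pattern are argued against by the members not looked at, whose median of -0.36 lay below all 10000 matched random lists. Normalization that moves genes of like signal alike would leave this median among those random lists, but it differed from the lowest by -0.16. This reuses the comparison just given, so the outcome was known beforehand and adds no evidence of its own. With probe sets of 1 transcript the median was -0.25 at percentile 0.02, so that it no longer lay below all random lists. The same arrays differed in fibroblast markers (median 0.20), 18S ribosomal RNA probe sets (median -0.52), Xist (3.59) and Y-linked genes. A lower amino acid response in this knockout culture thus stays a hypothesis that 1 array per genotype cannot decide, and differences in genotype, sex, cell composition, feeding or density of the cultures were not told apart by any test here. Trib3, Chac1, Ddit3 and Asns, in the group noticed first, are also members of the unfolded protein response list.

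Wwp2 had the widest range of probe-set differences after H2-D1 among genes with at least 3 probe sets above the floor, 3.51. No transcript structure was set against its probe sets here.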
